A study of Zea mays with 157 samples.

How the data were processed

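The libraries came from maize (Zea mays), from the inbred lines B73 and Mo17 and from an F1 hybrid between them. For each line the labels list 26 tissues, and for each tissue 1 circRNA library and 1 mRNA library, which gives 78 of each. A circRNA is a closed RNA ring made when a splice donor joins an upstream acceptor, and its reads cross that back-splice junction. Per the labels' protocols, each library pooled 3 separately extracted samples in equal amounts. Spread between plants was therefore not measured, and p-values of comparisons between lines, organs or leaves rest on the spread between tissues or leaf positions. Tests over circRNAs and their hosts take circRNAs as units, which are not independent. One total RNA library, labelled as the 1 cm ear of B73, could not be tied to a column and was not used.

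The circRNA tables hold RPM, values scaled to the reads of each library, as deposited by the authors. The smallest value of a library was taken as what 1 read was worth, and its inverse gave an implied depth of 10508700 to 21635600 reads in B73, 9998390 to 27527200 in Mo17 and 10161700 to 20234600 in F1. Values fell on fractions of that step as well as on whole steps, so whole reads were not recovered and no count test was run. Thinning to an equal depth rounded values to whole steps and rests on that reading of the smallest value. At 1 read lay 52.2% of the B73 values above 0, 52.6% of those of Mo17 and 46.0% of those of F1. The Mo17 mRNA columns each summed to between 1000010 and 1000070 and were read as TPM, deposited by the authors. The B73 and F1 mRNA columns are in a unit that no header or label names. B73 columns summed to between 337628 and 694778, and F1 columns to between 1147180 and 1653240. The F1 tables list identifiers from both parental genomes, so a shared feature and a feature of a single genome stand side by side in them. A pair of tables for the 1 cm tassel holds back-splice read counts and linear read counts per gene, as deposited. They are named for the tassel and match no single labelled sample. Whether they come from the total RNA library labelled as ear is open, so the organ behind their values is uncertain. They were treated as 1 library. Of all counts in the linear table, 81.8% lay outside annotated features, 10.5% had no unique alignment, 5.04% were not aligned, 1.55% had low alignment quality and 0.00696% were ambiguous. Those entries were kept out of every total, and 1.12% of counts were assigned to genes. The submitters' processing notes name HISAT, StringTie, TopHat and SAMtools without versions, and the build B73 RefGen_v4. The circRNA caller is not given in the sources used here.

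Tables of the lines were joined through the deposited lists of paired features. Of 127209 circRNAs in that list, 18312 had a position in both genomes, or 14.4%. None of the 82779 mRNA and host gene identifiers matched the reference gene table, which follows the assembly Zm-B73-REFERENCE-NAM-5.0, while 153 of 154 miRNA loci of the linear table did. The files do not pair gene identifiers with names. The 14 gene lists fixed before the data were examined could therefore not be tested, and genes are given by identifier. None of the reference's coordinates were used. F1 alleles are not apart in the tables, so allelic balance was not analysed here.

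Log2 values were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. For mRNA a pseudocount of 1 was added and genes at 1 or more in at least 3 libraries were kept. For circRNA the pseudocount was the smallest value above 0, and circRNAs above 0 in at least 5 libraries were kept. Fold changes are on the log2(value + pseudocount) scale, which understates the change of low features. The tissue, or the pair of leaf libraries, was a block. Pairing by tissue comes from the labels. Shared tissues had correlated deviations in every pair of lines, with a lowest correlation of 0.682 for mRNA and 0.238 for circRNA. For mRNA the same tissue was the best match in 22 of 26 cases for B73 with Mo17, 26 for B73 with F1 and 23 for Mo17 with F1. For circRNA it was so in 14, 13 and 18 of 26, so circRNA profiles identify the tissue poorly. The B73, Mo17 and F1 mRNA tables were normalized separately. The fixed design named no scaling between libraries. After the column sums were seen, and before any test result was seen, each mRNA library was divided by its median ratio to the geometric mean over genes at 1 or more in every library. This departs from testing within a single table, and every mRNA difference between lines depends on it.

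The number of circRNAs above 0 was compared with sign-flip permutation tests over tissues (100000 draws) and with an exact permutation test between organ classes, all two-sided. Sharing between lines was measured as the Jaccard index, the shared features as a percent of those found in either set. Tau, which runs from 0 for even values to 1 for a single tissue, measured tissue specificity. Features named in the text passed the threshold, moved the same way in at least 80% of informative pairs (or, for organ classes, in the class medians or means of B73 and of each other line that lists the feature) and, for mRNA, had a mean of at least 5 in a group. The fixed rule also asked for a gene name, which could not be applied, and up to 2 of the largest changes in each direction are given. The mid-parent value tested was the mean of the parents' log2 values. It is never above the log2 of their arithmetic mean, so an F1 at that arithmetic mean lies above it wherever the parents differ. Mid-parent levels printed as mean ± SD are arithmetic means of both parents, so their ratio differs from the tested change, which stands beside them. The limma steps were tested on simulated data drawn from the real means and residual spread with 200 changed features. At a 2-fold change, 98.5% of changed genes were recovered for B73 against Mo17 mRNA (9365 genes), 85.1% for L against N mRNA (7503 genes), 79.1% for B73 against Mo17 circRNA (4531 features) and 46.3% for L against N circRNA (1557 features). In that order, 8 of 193, 11 of 173, 2 of 140 and 3 of 95 calls fell on unchanged features. The simulated spread was normal on the log scale. Many circRNA values lie at 0 or at 1 read instead, so the circRNA recoveries are only rough. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1 was used for the rest. Alternatives covered pseudocounts, filters, scaling, library weights, blocks, left-out tissues and detection thresholds.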

Results

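The series measured circRNA and mRNA in 26 tissues of the maize inbreds B73 and Mo17 and their F1 hybrid, with 1 pooled library per tissue, line and RNA class. The tissues comprised 11 leaf samples, 9 shoot meristem, ear and tassel samples, and 6 others from root, stem and kernel. The tables listed 53558 circRNAs for B73, 44552 for Mo17 and 79239 for F1. In B73, 32142 circRNAs were found in 1 tissue only and 346 were found in all 26. The catalogue placed 80836 circRNAs on 13140 B73 host genes, with a median span of 1038 bp, and 64685 on 12098 Mo17 host genes, with a median span of 1110 bp. A single host, Zm00001d038163, carried 388 of the 80836 catalogued circRNAs, which are not limited to those listed for the B73 line.

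Leaves held fewer circRNAs than meristems and inflorescences. Averaged over the lines, leaf tissues had 4400 ± 896 circRNAs (SD, n = 11) and meristem and inflorescence tissues had 8637 ± 1390 (SD, n = 9). The exact permutation test gave p = 1.19e-05, or 1.79e-05 after Benjamini-Hochberg adjustment over 3 comparisons of number. It took each tissue as independent, although the 11 leaf tissues include 4 positions sampled with both suffix L and suffix N. The p-values may therefore be too small, here and in every other test of leaf against meristem and inflorescence. The 1 cm tassel of B73 had the most circRNAs of any B73 library, 11051, and the B73 embryo had the fewest, 2683. Summed circRNA abundance, a measure added after seeing the data, was 1317 ± 372 RPM in leaf (SD, n = 11) and 2569 ± 609 RPM in meristem and inflorescence (SD, n = 9). Leaf libraries were shallower, with 12709900 ± 1608710 implied reads in B73 (SD, n = 11) against 17301000 ± 3455470 (SD, n = 9). After thinning to an equal depth of 9998390 reads, an alternative added after seeing the data, leaf had 3847 ± 637 circRNAs (SD, n = 11) and meristem and inflorescence 6369 ± 1048 (SD, n = 9; exact permutation p = 2.38e-05).

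**Figure D1:**
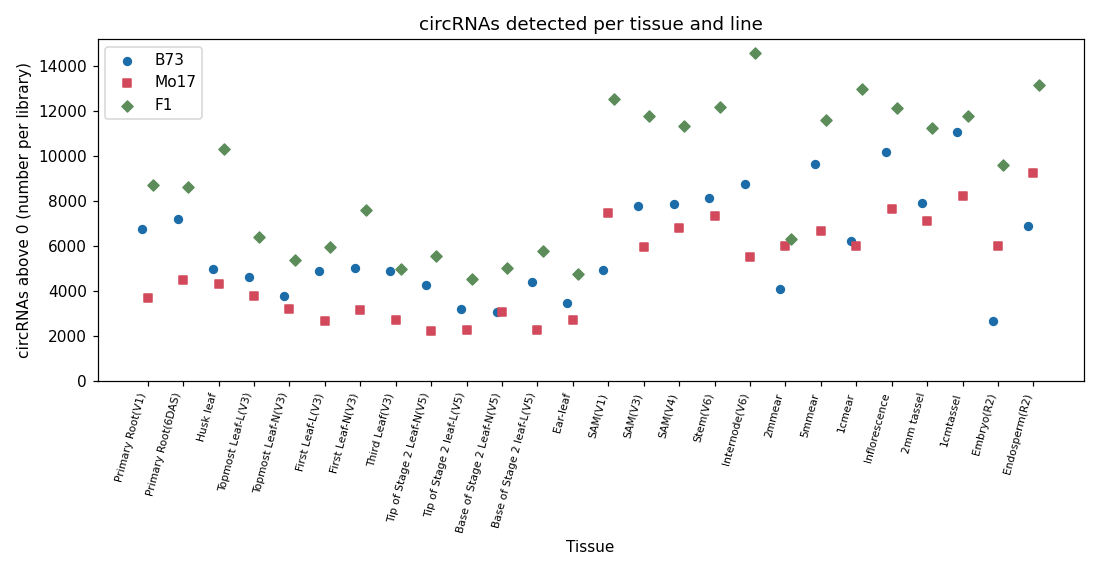
Number of circRNAs above 0 RPM (vertical axis) in each of the 26 tissues (horizontal axis), with 1 point per library for B73, Mo17 and F1. The B73 1 cm tassel stands at 11051 and the B73 embryo at 2683; the F1 table lists identifiers of both genomes, so F1 points are not on the same footing as those of the parents.

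Individual circRNAs followed the same organ difference in B73. Of 6061 circRNAs tested with limma and Benjamini-Hochberg adjustment, 401 were higher and 2019 lower in leaf. A 274 bp circRNA of host Zm00001d044099, on chromosome 3 from 219080582 to 219080855 (B73 RefGen_v4), reached 19.5 ± 7.30 RPM in leaf (SD, n = 11) and was listed at 0 in each of the 9 meristem and inflorescence libraries. One of 522 bp from host Zm00001d035212, on chromosome 6 from 10038925 to 10039446, had 8.34 ± 4.32 RPM in leaf (SD, n = 11) against 0.0243 ± 0.0483 RPM (SD, n = 9). In the other direction, a 408 bp circRNA of Zm00001d020392 (chromosome 7, 111022461 to 111022868) had 0.164 ± 0.290 RPM in leaf (SD, n = 11) against 7.36 ± 3.98 RPM (SD, n = 9). A 971 bp circRNA of Zm00001d004036 (chromosome 2, 77707084 to 77708054) had 0.167 ± 0.254 RPM in leaf (SD, n = 11) against 6.93 ± 1.81 RPM (SD, n = 9). Of the B73 calls tested in Mo17 too, 469 of 585 were called there, and 469 moved the same way. Scaling each library by its table total gave 605 higher and 1354 lower in leaf.

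mRNA differed between the same organs. Over all genes that passed the filter in B73, host or not, 7864 genes were higher and 10084 lower in leaf, of 23935 tested with limma and Benjamini-Hochberg adjustment. Zm00001d023516 had 6326 ± 5553 scaled abundance units in leaf (SD, n = 11) and 0.229 ± 0.310 in meristem and inflorescence (SD, n = 9). Zm00001d038163, the host with 388 catalogued circRNAs, had 4782 ± 2468 (SD, n = 11) against 1.19 ± 0.597 (SD, n = 9). Zm00001d030698 had 0.299 ± 0.673 in leaf (SD, n = 11) against 501 ± 336 (SD, n = 9), and Zm00001d050100 had 2.87 ± 6.60 (SD, n = 11) against 713 ± 278 (SD, n = 9). Of 6131 B73 calls on genes tested in Mo17 too, 5494 were called there and 5428 moved the same way. Values as deposited, without scaling, gave 4624 higher and 14862 lower in leaf. Of 400 circRNAs higher in leaf with a tested host, 308 had a host higher in leaf and 40 a host lower. Of 2008 circRNAs lower in leaf, 1469 had a host lower in leaf and 174 a host higher (Fisher's exact test across circRNAs, which are not independent, p = 2.71e-185).

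Across the 26 B73 tissues, circRNA and host mRNA were weakly related. The median Spearman correlation over 7793 circRNAs was 0.202, against a mean of 0.0296 over 1000 random host assignments (permutation p = 0.000999, the smallest these draws can give). The correlation was positive for 74.2% of circRNAs and above 0.5 for 17.4%. In subsets added after seeing the data, the median within the 11 leaf tissues was 0.118, against 0.000869 for random hosts, and within the 9 meristem and inflorescence tissues it was 0, against -0.068 for random hosts (permutation p = 0.000999 for each, the smallest these draws can give). The within-organ medians were lower than the pooled one. They rest on fewer tissues and on smaller sets of circRNAs, 2435 in leaf and 3921 in meristem and inflorescence. The medians are therefore not of the same circRNAs. Tissue specificity was higher for circRNAs than for their hosts, with a median tau 0.559 above the host median of 0.241. When host values were thinned to the level of each circRNA, the host median rose to 0.743, and the circRNA had the higher tau in 69.7% of cases. With tau taken on linear values, without thinning, the median was 0.852 for circRNAs and 0.527 for hosts.

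B73 libraries held more circRNAs than Mo17 libraries, 6024 ± 2342 (SD, n = 26) against 5020 ± 2135 (SD, n = 26), with B73 higher in 22 of 26 tissues. The paired permutation test gave p = 0.0111, and the adjusted value over the 3 comparisons of number was also 0.0111. Each line was counted in its own table, and the circRNAs are placed on separate B73 and Mo17 genomes. A difference between the lines therefore cannot be told apart from one between the genomes and host gene sets used. B73 was higher in all 11 leaf tissues and in both roots, while Mo17 was higher in embryo and endosperm. The Mo17 endosperm library was the deepest, with 27527200 implied reads against 17023500 in B73. At equal depth, an alternative added after seeing the data, endosperm had 5157 circRNAs in B73 and 5096 in Mo17, embryo 2495 in B73 and 4528 in Mo17, and B73 was higher in 10 of 11 leaf tissues. Over all tissues B73 then had 4699 ± 1481 (SD, n = 26) and Mo17 3761 ± 1217 (SD, n = 26; permutation p = 0.00037). For the numbers before thinning, a permutation test without the pairing by tissue gave p = 0.112. The circRNAs with a position in both genomes, a subset that leaves out most circRNAs found in a single line, numbered 1606 ± 565 in B73 (SD, n = 26) and 1699 ± 650 in Mo17 (SD, n = 26). B73 was higher in 13 of 26 tissues there, and the test did not pass the threshold (permutation p = 0.349).

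At the level of single circRNAs listed for both genomes, 409 were higher in B73 and 454 higher in Mo17, of 4531 tested with limma and Benjamini-Hochberg adjustment. On B73 chromosome 1, a 590 bp circRNA of Zm00001d033375 (261005788 to 261006377) had 3.11 ± 1.23 RPM in B73 (SD, n = 26) and 0.0198 ± 0.0450 RPM in Mo17 (SD, n = 26). On chromosome 10, a 1620 bp circRNA of Zm00001d025174 (107655971 to 107657590) had 6.50 ± 3.16 RPM in B73 (SD, n = 26) and 0.133 ± 0.167 RPM in Mo17 (SD, n = 26). A circRNA of Zm00001d023715 (chromosome 10, 16707424 to 16709023) had 0.183 ± 0.649 RPM in B73 (SD, n = 26) and 7.13 ± 6.31 RPM in Mo17 (SD, n = 26). One from Zm00001d047717 (chromosome 9, 139873717 to 139875255) had 0.140 ± 0.186 RPM in B73 (SD, n = 26) and 6.64 ± 5.96 RPM in Mo17 (SD, n = 26).

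The lines shared few circRNAs in any one tissue. The share of circRNAs found in both lines was 6.63 ± 0.495% (SD, n = 26 tissues) in the same tissue and 5.67 ± 0.218% (SD, n = 26) in different tissues. Between tissues of one line it was 20.3 ± 1.10% in B73 (SD, n = 26) and 19.7 ± 0.992% in Mo17 (SD, n = 26). Same-tissue sharing was below sharing within a line in 26 of 26 tissues (permutation p = 1e-05, the smallest the draws can give). A circRNA could count as shared between lines only with a listed position in both genomes. That held for 10302 of 53558 B73 and 10515 of 44552 Mo17 circRNAs. Within a line every circRNA could match itself, so the test cannot tell the pairing from a difference between the lines. The level also depends on the detection threshold. At 0.2 RPM or more the share was 11.7 ± 0.781% in the same tissue (SD, n = 26), against 36.8% within B73 and 36.3% within Mo17. Among circRNAs whose host genes are paired between the genomes, an alternative added after seeing the data, the share was 16.7 ± 1.22% in the same tissue (SD, n = 26), against 22.5% within B73 and 21.8% within Mo17, and still lower in 26 of 26 tissues. That filter kept all 7945 circRNAs listed in both lines and removed only others, so it raised the share by its construction. Among circRNAs with a position in both genomes, also an added alternative, the share was 25.8% in the same tissue. It was 25.7% within B73 and 25.6% within Mo17 (permutation p = 0.610), and that filter too removed only circRNAs not listed in both lines. Counted as host genes, again only those paired between the genomes, the share was 37.1 ± 4.45% (SD, n = 26), close to 39.2% within B73 and 38.3% within Mo17, and lower in 18 of 26 tissues (permutation p = 0.00559). Broadly found circRNAs were shared more often. Of B73 circRNAs found in 1 tissue, 9.33% were listed in Mo17 (95% exact binomial interval 9.01 to 9.65%), and of those found in all 26, 33.8% were (28.8 to 39.1%).

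**Figure D2:**
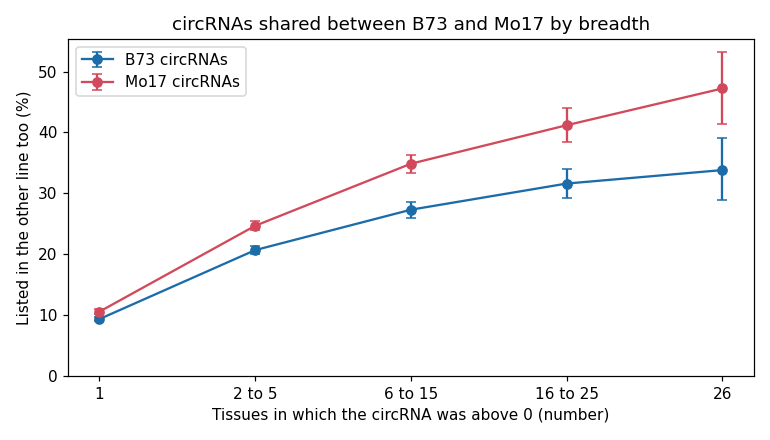
Percent of circRNAs listed in the other line (vertical axis) by the number of tissues in which the circRNA was above 0 (horizontal axis), with exact 95% binomial intervals as bars. In B73 the percent runs from 9.33 for circRNAs of 1 tissue to 33.8 for those of all 26.

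For mRNA shared by both genomes, 2274 genes were higher and 2591 lower in B73 than in Mo17, of 9365 tested with limma and Benjamini-Hochberg adjustment. Zm00001d011103 had 50.7 ± 16.5 scaled units in B73 (SD, n = 26) and 0.0156 ± 0.0477 in Mo17 (SD, n = 26). Zm00001d038650 had 45.9 ± 32.8 (SD, n = 26) against 0.00969 ± 0.0316 (SD, n = 26). Zm00001d025423 had 4.60 ± 11.5 in B73 (SD, n = 26) against 157 ± 57.4 in Mo17 (SD, n = 26), and Zm00001d012742 had 0.682 ± 0.305 (SD, n = 26) against 137 ± 53.3 (SD, n = 26). These tables were normalized separately, and values as deposited gave 540 higher and 6867 lower. Without the block for tissue the count fell to 1917. Tissue profiles, which do not depend on the scale between tables, had a median Spearman correlation of 0.820 over 7855 genes, against 0.292 over 1652 circRNAs, where randomly paired circRNAs gave 0.0924. For 288 circRNAs found in at least 20 tissues of both lines it was 0.535.

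F1 libraries listed more circRNAs than the mid-parent value, 9026 ± 3238 (SD, n = 26) against 5522 ± 2050 (SD, n = 26), in 26 of 26 tissues (permutation p = 1e-05, the smallest the draws can give; adjusted p = 1.79e-05). The F1 table lists identifiers of both genomes, so this number is not on the same footing as those of the parents. Among circRNAs with a position in both genomes, F1 had 2042 ± 693 (SD, n = 26) and the mid-parent value was 1653 ± 558 (SD, n = 26), with F1 higher in 23 of 26 tissues. In the same tissue the parents shared only 25.8% of these circRNAs. A library that held the sets of both parents would thus exceed their mean number without any change. Of the F1 circRNAs, 54.3% were listed in B73 or Mo17 and 36237 in neither. With limma and Benjamini-Hochberg adjustment, 118 circRNAs were above and 2 below the mid-parent value, of 6357. The mean of logs makes this balance lean to above by its construction. Over all listed circRNAs, F1 libraries also summed to more RPM than the mid-parent value, in 26 of 26 tissues. The sums, a measure added after seeing the data, were 2664 ± 1036 (SD, n = 26) against 1554 ± 639 (SD, n = 26). The RPM levels of F1 may thus not be on the same footing either. Scaling each library by its table total gave 76 above and 4 below. A circRNA of Zm00001d013435 (chromosome 5, 11323158 to 11324772) had 2.30 ± 1.69 RPM in F1 (SD, n = 26) against 0.0855 ± 0.163 RPM (SD, n = 26), with a log2 change of 4.83 against the mean of logs. The circRNA of Zm00001d023715 that was high in Mo17 had 7.62 ± 6.43 RPM (SD, n = 26) against 3.66 ± 3.17 RPM (SD, n = 26), with a log2 change of 3.25, or 1.05 with the arithmetic mid-parent. A circRNA of Zm00001d023738 (chromosome 10, 18095511 to 18097713) had 0.0305 ± 0.0672 RPM in F1 (SD, n = 26) against 0.0925 ± 0.0920 RPM (SD, n = 26). Its log2 change was -0.779, and the call was lost without the block, with a pseudocount 10 times larger and with a filter of 2 libraries. Against the arithmetic mid-parent, 21 were above and 4 below, and without the block for tissue 72 were called.

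For mRNA, 593 genes were above and 155 below the mid-parent value, of 9712 tested with limma and Benjamini-Hochberg adjustment. This balance too leans to above through the mean of logs. Zm00001d021789 had 24.9 ± 11.8 scaled units in F1 (SD, n = 26) against 1.14 ± 1.11 (SD, n = 26), and Zm00001d023657 had 41.2 ± 13.2 (SD, n = 26) against 4.70 ± 5.02 (SD, n = 26). The log2 changes against the mean of logs were 3.67 and 3.57. Zm00001d021001 had 2.91 ± 0.773 in F1 (SD, n = 26) against 7.81 ± 1.94 (SD, n = 26), with a log2 change of -0.755, or -1.17 with the arithmetic mid-parent. Zm00001d023669 had 5.96 ± 5.53 (SD, n = 26) against 11.6 ± 13.6 (SD, n = 26), with a log2 change of -0.595 that did not pass without the block. The F1 table was normalized separately. The balance of directions turned with the arithmetic mid-parent, at 468 above and 745 below, and quantile normalization gave 544 above and 577 below. Without the block for tissue 404 genes were called.

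Leaves carried the suffix L or N at 4 positions, whose meaning the labels do not give. Over 12 pairs, 967 genes were higher and 1321 lower in L, of 7503 tested with limma and Benjamini-Hochberg adjustment. The 12 pairs are the same 4 positions in each of 3 lines. At most the 4 positions are independent of each other, while the fit took every pair as a replicate. Zm00001d019479 had 97.1 ± 59.1 scaled units in L (SD, n = 12) and 11.2 ± 26.9 in N (SD, n = 12), in 11 of 12 pairs. Zm00001d043045 had 82.7 ± 47.8 in L (SD, n = 12) and 14.4 ± 40.1 in N (SD, n = 12). Zm00001d037060 had 4.99 ± 9.95 in L (SD, n = 12) and 46.3 ± 34.7 in N (SD, n = 12), also in 11 of 12 pairs, and Zm00001d014291 had 25.996 ± 39.7 in L (SD, n = 12) and 132 ± 46.3 in N (SD, n = 12). Values as deposited gave 553 higher and 2017 lower, and at 2-fold or more 236 were higher and 83 lower. The libraries labelled Mo17 tip L and Mo17 tip N went against the other pairs. Of 1134 genes called with the same sign in B73 alone and in F1 alone, 2.12% had that sign in the Mo17 tip pair, against 94.5%, 95.1% and 89.2% at the other Mo17 positions. Without the Mo17 tip libraries, an alternative added after seeing the data, 3552 genes were called. The log2 change then went from 3.79 to 4.53 for Zm00001d019479, from 3.70 to 4.50 for Zm00001d043045 and from -3.32 to -4.06 for Zm00001d037060. With limma, 0 genes were called without the base, first or topmost leaf, or in Mo17 alone, where 2250, 2259, 2726 and 125 had an unadjusted p under 0.05. Those fits kept the Mo17 tip pair, as did the fit of all pairs. Without the tip position 2879 genes were called, in B73 alone 1540 and in F1 alone 1699. Without the block for pairs 1005 were called. For circRNA, limma called 0 of 1557 between L and N, with 77 at an unadjusted p under 0.05.

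**Figure D3:**
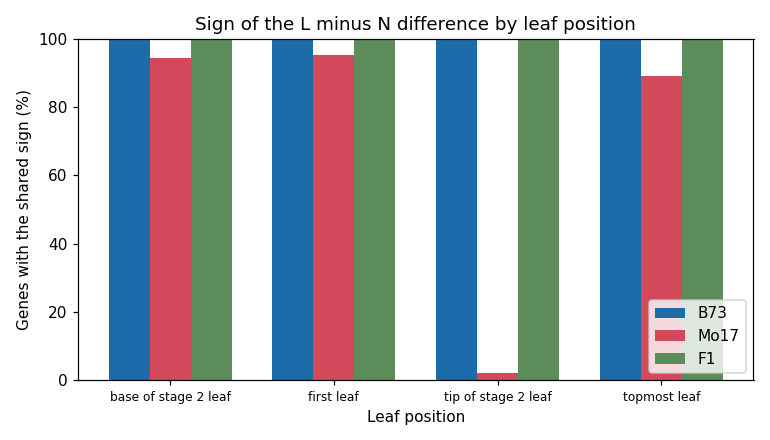
Percent of 1134 genes whose L minus N difference had the sign shared by B73 and F1 (vertical axis) at each of 4 leaf positions (horizontal axis), with 1 bar per line. The genes were chosen in B73 and F1, so only the Mo17 bars test them; the Mo17 tip stands at 2.12% and the other Mo17 positions at 94.5, 95.1 and 89.2%.

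Tip and base of the stage 2 leaf differed in 846 genes over 6 pairs, 386 higher and 460 lower in the tip, of 7046 tested with limma and Benjamini-Hochberg adjustment. The 6 pairs are the suffixes L and N of this leaf in each of 3 lines, so they are not independent replicates. Zm00001d024963 had 56.4 ± 15.5 scaled units in the tip and 4.78 ± 2.25 in the base, and Zm00001d024996 had 54.8 ± 49.6 in the tip and 2.90 ± 1.62 in the base. Zm00001d004330 had 3.09 ± 3.97 in the tip and 397 ± 353 in the base, and Zm00001d052683 had 0.593 ± 0.453 in the tip and 113 ± 93.5 in the base (SD, n = 6 for each). The Mo17 pairs include the doubted tip libraries, and without those 707 genes were higher and 562 lower in the tip, with a log2 change of 2.87 instead of 3.48 for Zm00001d024996. Values as deposited gave 187 higher and 1915 lower. Leaving out the F1 L pair gave 263 genes, and 524 were called without the block for pairs.

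The junction tables named for the 1 cm tassel, whose library is uncertain, held 2539 back-splice junctions with 13426 reads, of which 2470 were exonic and 69 intronic. Exonic circRNAs spanned a median of 4 exons, and 7.04% had a single exon. In the 1692 host genes, back-splice reads were 29.2% of back-splice and linear counts together (95% exact binomial interval 28.8 to 29.6%, counting error only), and 59.4% over junctions with 5 or more reads, a filter on back-splice reads that raises this share by its construction. In the 323 hosts with at least 10 linear counts, the median ratio of back-splice to linear counts was 8.33%. Only 1.12% of all counts in the linear table were assigned to genes. The linear side may therefore be understated, and these shares cannot be read as the circular fraction of the RNA. Of the junctions, 66.2% were above 0 in the B73 1 cm tassel circRNA library.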

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

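The label test on the Mo17 tip pair was written before its result was seen, although the profile comparison that prompted it had been seen; the tests on depth, on sharing and on other groupings were chosen after the results they bear on.

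The L minus N difference of the Mo17 tip pair ran against B73 and F1, with 2.12% of 1134 genes keeping the shared sign. A swap of the 2 labels required under 25% there and at least 75% at each other Mo17 position, and both held. By mRNA profile, seen first, the library labelled tip L in Mo17 correlated at 0.916 with tip N of F1 and at 0.747 with tip L of F1. The percent was read from the same Mo17 libraries, so it repeats that match and is no separate evidence. A swap may be a candidate explanation, and a reversed response of Mo17 at that single position stays as open, since no second library of it exists. The circRNA profiles decide nothing here: B73 tip N correlated at 0.506 with Mo17 tip N and 0.417 with Mo17 tip L, while Mo17 tip L correlated at 0.486 with F1 tip N and 0.434 with F1 tip L. B73 tip N correlated at 0.547 with F1 tip L and 0.537 with F1 tip N, so they do not separate the suffixes.

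Fewer circRNAs in leaf could come from shallower libraries, yet the ratio of leaf to meristem and inflorescence was still 0.604 at equal depth, with the smallest value of each library read as 1 read, a reading the fractional values leave in doubt. The ratio of the number at 0.2 RPM or more, which does not use that reading, was 0.573. Together these argue against depth as the whole cause. Other RNA in the leaf reads behind each RPM value cannot be told apart from fewer circRNAs, since the summed RPM ratio of 0.513 goes with both and no table gives the makeup of the reads. A difference between organs, which the design names, remains open and untested.

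Low sharing between B73 and Mo17 was weighed against rare detection and against the pairing of positions between genomes. Rare detection as the whole cause is argued against, since at 0.2 RPM or more the share between lines was 0.319 of that between tissues of a line. Among circRNAs with a partner the ratio was 1.01. That filter kept all 7945 circRNAs listed in both lines and removed only others, so that ratio decides nothing. Among circRNAs of paired host genes the ratio was 0.753 against 0.332 for all, but the filter removed only circRNAs listed in 1 line, so this decides nothing either, and the pairing cannot be told apart from a difference between the lines.

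The lead of B73 over Mo17 in circRNA number differed between leaf and meristem and inflorescence tissues (exact permutation p = 0.0228). Among 21 groups of 9 meristem and inflorescence values, 6 extreme values stood apart by a test that chance passes in about 1 of 20 groups. They are not independent, since 3 belong to the F1 2 mm ear and 2 to the Mo17 1 cm tassel. In the 2 mm ear of F1, 6323 circRNAs were found, 5641 after thinning, with 33593 genes at 1 or more. The most abundant circRNA took 6.56% of the B73 2 mm ear. The Mo17 1 cm tassel had 2941 RPM in sum and 6129 circRNAs after thinning. In the linear table named for the 1 cm tassel, miRNA loci held 201 counts, 172 of them at zma-MIR482.

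Other groupings of the same libraries were drawn for each limma comparison. For mRNA between B73 and Mo17, 1 of 100 splits, the real one, gave 4865 genes, and the highest other gave 3. For F1 against mid-parent the values were 748 and 0, for leaf against meristem and inflorescence 17948 and 4996, and for L against N 2288 and 1147. For tip against base, 1 of 32 splits gave 846 genes and the highest other gave 0. The circRNA values were 863 and 0 between lines, 120 and 47 for F1, and 2420 and 384 between organs. In each of these the real split gave the most calls of the splits drawn. This argues against chance but cannot exclude it, since few splits were drawn and some others still gave many calls. The splits also took tissues or pairs as independent, which leaf libraries of the same position are not. For circRNA between L and N the real count was 0, which 100 of 100 splits reached, with a highest other of 2.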

How the results depend on the processing

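Of 131 alternative values of the comparisons, 90 kept their side of the threshold, or for counts stayed within 1.5 times; 15 of those set 0 circRNAs against 0 for L and N and say nothing about stability, which leaves 75. A further 38 moved, 2 reversed and 1 lost significance. F1 mRNA under quantile normalization kept its count within 1.5 times but not its balance, 544 above and 577 below. The unscaled, arithmetic, Mo17-tip, equal-depth and summed RPM settings were chosen after seeing the data. So were partner-only and paired-host circRNAs for sharing, host correlations within an organ, circRNA organs without husk leaf and ear-leaf, and circRNA leave-outs and single lines for L and N, and causes were not tested. Asking for at least 2-fold gave 604 genes between lines, 108 for F1, 11005 between organs, 319 for L and N (236 higher, 83 lower in L) and 356 for tip and base, and 372, 49 circRNAs for lines and F1. Without the block or pairing, counts were 1917, 404, 1005 and 524 genes in lines, F1, L against N and tip against base, 72 circRNAs in F1, and the B73 lead of 1004 circRNAs had p = 0.112. Values as deposited gave 7407 genes between lines, 2570 for L and N (553 higher, 2017 lower) and 2102 for tip and base (187 higher, 1915 lower). Library weights gave 1228 genes for F1 (the weights did not converge), 3749 for L and N and 1572 for tip and base. F1 gave 1156 genes with no filter, 1213 with an arithmetic mid-parent, and for circRNA 25 with that mid-parent and 65 with a pseudocount 10 times larger. Between organs the number tested moved with the count: F1 in place of B73 gave 30753 of 41522 genes, against 17948 of 23935, and 4022 of 8760 circRNAs, against 2420 of 6061, and a filter of 10 libraries 1369 of 2680 circRNAs. Leaving out a leaf position gave 0 to 2879 genes for L and N, and leaving out a pair 263 to 1023 for tip and base. Mo17 alone gave 0 genes in both (125 and 196 at an unadjusted limma p under 0.05), B73 alone 169 and F1 alone 36 for tip and base. Without the Mo17 tip libraries L and N gave 3552 genes. Partner-only circRNAs, which leave out most circRNAs of a single line, gave a line difference in number of -92.7 (p = 0.349) and a sharing of 25.8%, against 25.7% within B73 and 25.6% within Mo17 (permutation p = 0.610). Back-splice shares were 35.995% at 2 reads and 59.4% at 5, where the filter is on the numerator. Named features kept their direction in 278 fits and lost significance in 23. Allelic balance and the gene lists were not run, since alleles are not apart and no mRNA or host gene identifier matched a name. At 1 read lay 52.2% of B73 circRNA values, which limits single-tissue calls.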

Other observations

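Mitochondrial circRNAs were listed for B73 only. The B73 table held 371 of them, with 3.69 ± 1.22 RPM in sum in meristem and inflorescence (SD, n = 9) and 1.18 ± 0.910 RPM in leaf (SD, n = 11; exact permutation p = 0.000155). All B73 circRNAs together were also lower in leaf, at 1311 against 2316 RPM on average. As a percent of summed RPM, mitochondrial circRNAs took 0.128 to 0.211% in meristem and inflorescence. Husk leaf (0.197%) and ear-leaf (0.188%) lay within that range, and the other leaf libraries at 0.0424 to 0.0926% lay below it. The highest sum, 5.96 RPM, was in the stem at stage V6. The F1 table listed 0 of them, and the Mo17 catalogue places 0 circRNAs on a mitochondrial sequence, so the lines were not compared.

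The circRNAs of a library that occurred nowhere else in that line were most numerous in the B73 1 cm tassel, with 2655 or 24.02% of its total, the Mo17 endosperm, with 2457 or 26.6%, and the F1 internode, with 3771 or 25.9%. The largest share in B73 was that of the stem, 26.7%, and the smallest that of the base leaf N, 13.5%; in Mo17 the smallest was that of the library labelled tip leaf N, 13.2%. These values were not corrected for depth, and the Mo17 endosperm library was the deepest. Of the F1 circRNAs listed in neither parent, 85.2% were found in 1 tissue only.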
